A study of Mus musculus with 6 samples.

How the data were processed

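The samples were 6 bulk RNA-seq libraries of mouse prefrontal cortex, 2 per group. Per the labels' protocols, total RNA was depleted of ribosomal RNA, made into stranded libraries and sequenced on an Illumina instrument, and the samples of each group are biological duplicates, which the series' design describes as separate mice. The wild-type animals are described as a cross of C57BL/6 and C3H. The deposited values are raw read counts per gene symbol, 1 file per library with 54134 entries, and per the submitters' processing notes they come from featureCounts after trimming with cutadapt and alignment with TopHat2, with SAMtools and edgeR also named and mm10 (GRCm38) as the genome build. Versions, the annotation release and the strand setting are not given in the sources used here, so overlapping and antisense genes may share counts.

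The files were checked before use. All counts were whole numbers. All 37 mitochondrial genes listed stood at 0, and 26 symbols had been turned into dates, 2 of these occurring 2 times, with at most 0.298% of a library's reads; these were kept out of the named genes. The small nuclear RNA Rn7sk took 2.64% to 3.76% of reads. Of the tested symbols 98.4% matched GENCODE release M21 (GRCm38), which supplied coordinates, exonic length and GC content. Libraries of the same group differed by more than sampling noise (chi-square per degree of freedom 9.94 to 13.3), so none was a repeat of another. Depth ran from 14133834 to 28646960 counted reads, and 3 counts in a library, the floor used here, correspond to 0.105 to 0.212 CPM; this floor covers counting error only.

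The tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were filtered with filterByExpr, libraries were scaled by TMM, and a robust quasi-likelihood model with 3 groups was fitted to all 6 libraries, which leaves 3 residual degrees of freedom and a biological coefficient of variation of 11.5%. Tests were two-sided with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. At an unadjusted p under 0.05, 2628, 1066 and 2941 genes passed in the comparisons of Shank3 vehicle with wild type, GSK-LSD1 with Shank3 vehicle, and GSK-LSD1 with wild type. These were 14.0%, 5.7% and 15.7% of tested genes, where chance gives 5%. The libraries of both groups did not overlap for 46.2%, 33.6% and 45.8% of tested genes, where chance gives 33.3%.

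Before the data were examined, 32 testable gene lists (functions and cell type markers), the rule for named genes, the tests and most alternatives were fixed. Named genes were Shank3 and Kdm1a, the 12 genes per direction with the smallest adjusted p among those passing with a mean CPM of at least 1 and no overlap between groups, leaving out predicted genes and pseudogenes (6 by unadjusted p where fewer than 6 passed), and up to 4 members of each list with the smallest p. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, over 96 tests of 32 lists; 55 were called. With an estimated correlation 0 were called (12 at an unadjusted p under 0.05, smallest adjusted p 0.180), and with fry 0 (22 at an unadjusted p under 0.05, smallest adjusted p 0.0636). The size of the correlation alone does not account for the lost calls. For autism risk genes in Shank3 vehicle against wild type the estimate was 0.00179, below the preset 0.01. Their unadjusted camera p still went from 1.82e-12 to 0.00375. The very small p-values at the preset correlation therefore depend on that setting of camera. The sex-linked list was too short for a test. Nlgn4l, Hbb-b1 and Hbb-b2 were not measured. Lists of hypothalamus, septum and preoptic area markers and of thalamus markers, and families of genes sharing a name prefix, were added after the data were seen.

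The procedure was tested on simulated counts drawn from the real means, library sizes and spread, with 200 genes changed, over 5 runs per comparison. For Shank3 vehicle against wild type (18237 genes) it recovered 36.1%, 52.2% and 73.3% of genes changed 1.5-fold, 2-fold and 3-fold. For GSK-LSD1 against Shank3 vehicle (18221 genes) the shares were 32.8%, 59.1% and 71.2%, and for GSK-LSD1 against wild type (18185 genes) 32.2%, 63.9% and 75.8%. Unchanged genes made up 13.5%, 12.6% and 15.0% of calls, more than the nominal 5%, so some called genes here are false. These shares belong to runs with 200 changed genes and cannot be carried over to the real calls. For GSK-LSD1 against Shank3 vehicle only 20 genes were called, and the false share among them may be much larger.

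Alternatives were RLE, upper quartile and library size scaling, other filters, DESeq2, limma-voom, a fit that was not robust, only the 4 libraries of a comparison, the replicate number as a block, the 20 most abundant genes left out, other thresholds, and each library left out in turn. A correction for length and GC content and a model with the oligodendrocyte marker level as a covariate were added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.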

Results

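RNA from the prefrontal cortex of mice aged 6 to 8 weeks was profiled by strand-specific sequencing of ribosome-depleted total RNA. There were 3 groups of 2 libraries each: wild-type controls given vehicle, mice heterozygous for a C-terminal deletion of Shank3 given vehicle, and the same mutants given GSK-LSD1. Shank3 encodes a scaffold of the postsynaptic density at excitatory synapses, and its loss is tied to autism. GSK-LSD1 is an inhibitor of LSD1 (Kdm1a), a demethylase of histone H3. The wild-type libraries held 15194848 and 28646960 counted reads, the Shank3 vehicle libraries 21734688 and 21488920, and the GSK-LSD1 libraries 23538125 and 14133834. After removal of low counts 18705 genes were tested. The design allows 3 comparisons: the effect of the mutation under vehicle, the effect of the inhibitor in the mutants, and what still separates treated mutants from controls. Levels are given as CPM (read counts scaled to the library total after TMM adjustment), mean ± SD over 2 libraries, and log2 fold changes with an approximate standard error (SE). The SE is the absolute log2 fold change divided by the square root of the F statistic of edgeR's test.

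Shank3, on chromosome 15 from 89499623 to 89560261 (plus strand, GRCm38), was counted at 156 ± 4.90 CPM in wild type, 160.1 ± 20.2 in Shank3 vehicle and 154 ± 7.54 with GSK-LSD1. Neither its difference between mutant and wild type (0.03 ± 0.11, adjusted p = 0.937) nor that between treated and untreated mutants (-0.06 ± 0.11, adjusted p = 0.999) passed the test. A count over the whole gene includes exons outside the deleted part, so this value checks the genotype labels only in a limited way. Kdm1a, the target of the inhibitor, on chromosome 4 from 136550540 to 136602723 (minus strand), lay at 97.5 ± 6.22, 91.7 ± 7.68 and 92.6 ± 3.77 CPM in the same order, and no comparison of it passed. Xist was at 0 reads in all 6 libraries, which at these depths allows at most 0.212 CPM of the unscaled total, while the Y-linked Ddx3y lay between 51.3 and 72.1 CPM. The group medians of the tested sex-linked markers differed by 0.22 between Shank3 vehicle and wild type, -0.05 between treated and untreated mutants, and 0.20 between treated mutants and wild type, with 0 of 4 passing in each.

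In the mutants given vehicle, genes of ion channels and synapses were among those lower than in wild type, and 2 astrocyte markers were among those higher. Scube1, a secreted and membrane-bound EGF-domain protein, fell from 106 ± 7.71 to 59.4 ± 0.436 CPM (log2 fold change -0.84 ± 0.10, n = 2 libraries per group, edgeR adjusted p = 0.00255). Grin2b, an NMDA receptor subunit, fell from 1647 ± 295 to 989 ± 22.2 CPM (-0.74 ± 0.13, adjusted p = 0.0178). Reln, an extracellular glycoprotein that guides cortical layering, fell from 193 ± 1.49 to 123 ± 2.09 CPM (-0.64 ± 0.10). Gja1, the astrocytic connexin, rose from 151 ± 15.9 to 229.9 ± 16.1 CPM (0.60 ± 0.11, adjusted p = 0.0222). In all, 238 of 18705 genes passed at an adjusted p under 0.05, 52 higher and 186 lower in the mutants, with median log2 fold changes of 0.70 and -0.55.

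The lower genes included members of each synaptic list fixed in advance. Among 40 voltage-gated channels 11 fell, 0 rose and 29 did not pass (22 fell adjusted over the list alone). The calcium channels Cacna1b (-0.64 ± 0.12) and Cacna1e (-0.62 ± 0.13), the potassium channel Kcnb2 (-0.50 ± 0.11) and the sodium channel Scn8a (-0.52 ± 0.11) were among them. The list's median was -0.32, and camera with a preset correlation called it (adjusted p = 6.37e-15, and adjusted p = 0.256 with an estimated correlation). Of 17 ionotropic glutamate receptor subunits 3 fell (10 adjusted over the list alone): Grin2b, Grin3a (-0.47 ± 0.11) and Grik5 (-0.52 ± 0.12). Their median was -0.32 (adjusted p = 2.56e-10, and adjusted p = 0.256 with an estimated correlation). Of 30 presynaptic vesicle proteins 5 fell (10 lower and 2 higher adjusted over the list alone), among them the active zone scaffolds Bsn (-0.77 ± 0.14) and Pclo (-0.64 ± 0.13) and the synapsin Syn1 (-0.72 ± 0.13). That list had a median of -0.25 and an adjusted p of 2.53e-08 (adjusted p = 0.315 with an estimated correlation). Of 30 postsynaptic scaffolds and adhesion proteins 4 fell (10 adjusted over the list alone), among them Nlgn2 (-0.66 ± 0.12), Iqsec2 (-0.57 ± 0.13) and Lrfn1 (-0.53 ± 0.13). Their median was -0.20 (adjusted p = 6.41e-08, and adjusted p = 0.341 with an estimated correlation). Each of these 4 lists was called with the preset correlation whichever library was left out.

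Of 49 autism risk genes 3 fell over all genes and 18 adjusted over the list alone, Reln and Grin2b among them, and 0 rose. The median was -0.22 (adjusted p = 2.50e-11, and adjusted p = 0.180 with an estimated correlation). Of 14 GABA receptor subunits 2 fell (3 adjusted over the list alone), Gabrb1 (-0.51 ± 0.11) and Gabrg3 (-0.46 ± 0.10), with a list median of -0.20 (adjusted p = 3.76e-04, and adjusted p = 0.471 with an estimated correlation). Of 38 monoamine, acetylcholine and peptide receptors 2 fell (3 adjusted over the list alone), the somatostatin receptor Sstr2 (-0.58 ± 0.12) and the muscarinic receptor Chrm1 (-0.50 ± 0.11), with a median of -0.21 (adjusted p = 3.96e-06, and adjusted p = 0.351 with an estimated correlation). Of 25 immediate early genes, which neurons switch on with activity, 4 fell (5 adjusted over the list alone). These were Egr4 (-0.94 ± 0.15), Egr2 (-1.20 ± 0.25), Fosb (-0.96 ± 0.20) and Nptx2 (-0.57 ± 0.12), and the list's median was -0.31 (adjusted p = 2.37e-06, and adjusted p = 0.431 with an estimated correlation). Of 38 other histone methyltransferases and demethylases 0 passed edgeR's test over all genes (11 at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma-voom) and 1 fell adjusted over the list alone, with a median of -0.17 (adjusted p = 4.24e-06, and adjusted p = 0.337 with an estimated correlation). Among 32 actin regulators Wasf1 (-0.60 ± 0.11) and Cyfip2 (-0.47 ± 0.11), both of the WAVE complex, fell (3 adjusted over the list alone). The median of that list, -0.04, turned to 0.03 when libraries were scaled by size alone (adjusted p = 0.00967, and adjusted p = 0.50 with an estimated correlation). With the oligodendrocyte level in the model, a setting chosen after the data were seen, the medians of the GABA receptors and actin regulators turned to 0.03 and 0.08. With a library left out, the median of the immediate early genes went to -0.59 (wild-type 1), -0.15 (wild-type 2) and -0.48 (Shank3 vehicle 1). The GABA receptor call was lost without wild-type library 2 (median -0.07) and the actin call without Shank3 vehicle library 2 (-0.03), and the actin median was -0.12 without wild-type library 1 and -0.09 without Shank3 vehicle library 1.

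Some markers of cell types passed in the same comparison. Of 10 excitatory neuron markers 1 fell (4 adjusted over the list alone). Their median was -0.28 (adjusted p = 4.71e-05, and adjusted p = 0.337 with an estimated correlation). The 14 inhibitory neuron markers had a median of 0.12 and the list was not called (adjusted p = 0.566). Of 12 astrocyte markers 2 rose (9 adjusted over the list alone), Gja1 and the water channel Aqp4 (0.51 ± 0.11), and the median was 0.43 (adjusted p = 2.41e-10, and adjusted p = 0.351 with an estimated correlation). The 14 oligodendrocyte markers had a median of 0.93 with 0 passing edgeR's test over all genes or over the list alone, 2 at an unadjusted p under 0.05, 1 called by DESeq2 and 3 by limma-voom (adjusted p = 4.85e-07, and adjusted p = 0.50 with an estimated correlation). Mbp, a myelin protein, lay at 762 ± 1.61 CPM in wild type, 1856 ± 28.7 in Shank3 vehicle and 1240 ± 739 with GSK-LSD1, where the 2 libraries held 717 and 1763 CPM. Of 10 oligodendrocyte precursor markers Gpr17 rose (0.94 ± 0.16), 2 rose adjusted over the list alone, and the median was 0.46 (adjusted p = 1.58e-05, and adjusted p = 0.337 with an estimated correlation). Of 14 microglia markers Itgam rose (1.22 ± 0.27), 3 rose adjusted over the list alone, and the median was 0.27 (adjusted p = 5.09e-05, and adjusted p = 0.471 with an estimated correlation). Of 13 endothelial markers Itm2a rose (0.48 ± 0.11), 1 adjusted over the list alone, with a median of 0.29 (adjusted p = 0.00615, and adjusted p = 0.530 with an estimated correlation). Without wild-type library 1 the medians were 0.28 for astrocyte, -0.17 for excitatory, 0.17 for microglia and 0.12 for endothelial markers. Without Shank3 vehicle library 1 they were 0.43 for microglia and 0.44 for endothelial markers, and without library 2 0.17 and 0.18. The endothelial call was lost without wild-type library 1 and without Shank3 vehicle library 2.

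**Figure D1:**
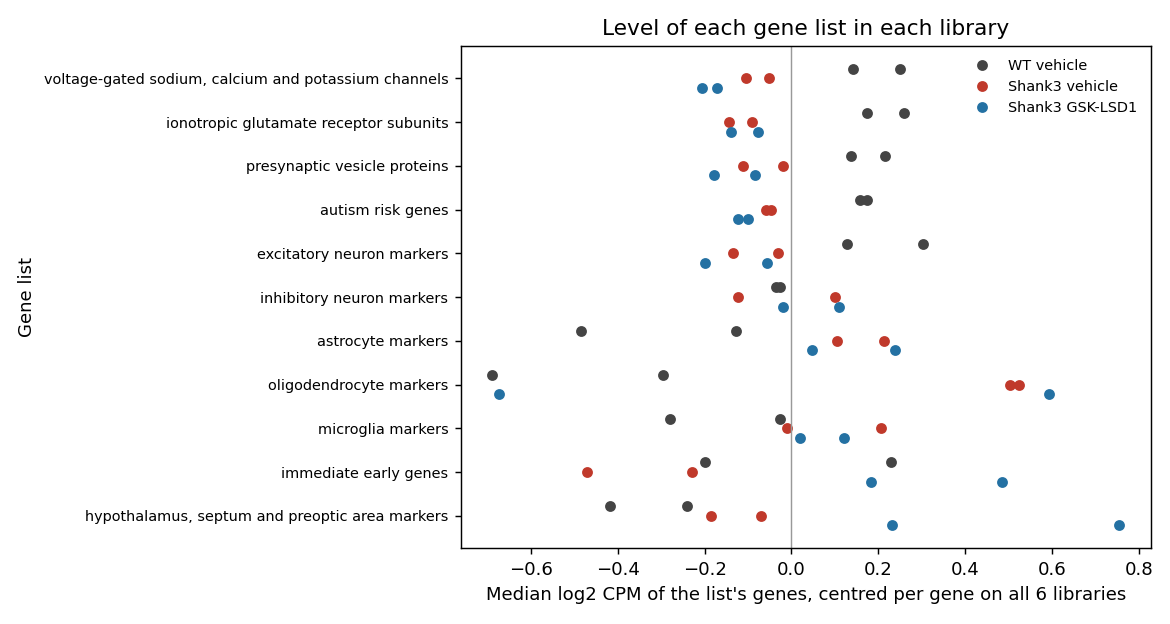
Each point is 1 library; the horizontal axis is the median log2 CPM of a list's genes after each gene was centred on all 6 libraries, and the vertical axis names the list. Wild-type libraries lie higher than both groups of mutants for channels, glutamate receptors, presynaptic proteins, autism risk genes and excitatory neuron markers, and the GSK-LSD1 libraries lie far apart for oligodendrocyte markers (-0.67 and 0.59).

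The remaining lists were not called between mutant and wild type, or lost their call with at least 1 library left out. The mitochondrial respiratory chain had a median of 0.15 with 46 of 52 members positive, 0 passing edgeR's test (7 at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma-voom) and 3 higher adjusted over the list alone (adjusted p = 4.22e-05, and adjusted p = 0.658 with an estimated correlation). Among 19 glucocorticoid-responsive genes Tsc22d3 rose (0.53 ± 0.11) and the clock gene Per1 fell (-0.53 ± 0.13), with 4 higher and 1 lower adjusted over the list alone. That list had a median of 0.05 (adjusted p = 0.0440, and adjusted p = 0.530 with an estimated correlation). The 25 interferon response genes had a median of 0.17 with 0 passing over all genes or over the list alone, 4 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom (adjusted p = 0.0491, and adjusted p = 0.351 with an estimated correlation). Both calls were lost with any of the 6 libraries left out: in the order of the libraries given above, the medians were 0.09, 0.12, 0.18, 0.14, 0.05 and 0.05 for glucocorticoid and 0.06, 0.25, 0.11, 0.14, 0.16 and 0.15 for interferon genes. The respiratory chain call was lost without wild-type library 1 (median 0.07) and without Shank3 vehicle library 1 (0.05), and the median was 0.23 without Shank3 vehicle library 2. Camera did not call the 14 members of the LSD1-CoREST complex and its partners (median -0.09), 48 ribosomal proteins (0.02), 28 heat shock genes (0.05), 28 extracellular matrix genes (-0.04, mean 0.06, median 0.04 with library size scaling), upper layer markers (-0.14) or deep layer markers (-0.03, or 0.04 with library size scaling). Nor did it call markers of striatal neurons (0.06, with the test pointing lower), pericytes (0.06), meningeal fibroblasts (-0.16, mean 0.15), choroid plexus (0.57), ependymal cells (0.40) or erythrocytes (-0.56). Adjusted p-values of these lists ran from 0.0931 to 0.858. Within them the matrix genes Sparc (0.68 ± 0.12) and Tnr (-0.59 ± 0.11), the pericyte marker Rgs5 (0.58 ± 0.11) and the ribosomal Rps2, given below, passed.

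The number of calls in this comparison depended on single libraries. Without wild-type library 1 only 6 genes passed, and 416 passed without wild-type library 2. The count was 8 without Shank3 vehicle library 1 and 20 without library 2, while leaving out GSK-LSD1 library 1 or 2 gave 626 or 656. Scube1 passed in each fit made, and each of the other named genes that passed in this comparison failed in at least 1 of them. Scaling by library size alone gave 15 higher and 20 lower genes, upper quartile scaling 45 and 96, and a fit without the robust option 11 genes in all. A correction for transcript length and GC content, chosen after the data were seen, left 26 higher and 35 lower genes, and a model with the oligodendrocyte level, also chosen then, 6 higher and 94 lower.

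The called genes differed from others in length. The median exonic length was 7.79 kb for genes lower in Shank3 vehicle and 4.45 kb for those higher, against 3.79 kb for all tested genes with annotation. In 13782 of these with a mean log2 CPM above 1, levels centred on all 6 libraries correlated with log2 length at r = 0.15 in each wild-type library, -0.13 and 0.09 in the Shank3 vehicle libraries, and -0.16 and -0.13 in the GSK-LSD1 libraries. With the log2 fold changes of Shank3 vehicle against wild type, length had a Spearman correlation of -0.16. It was -0.18 for GSK-LSD1 against Shank3 vehicle and -0.26 for GSK-LSD1 against wild type. For GC content the Spearman correlations in the same order of comparisons were -0.18, 0.21 and -0.00935. The 2 comparisons that share the Shank3 vehicle libraries thus had opposite trends on GC content. Per library, levels correlated with GC content at r = 0.19 and -0.10 in wild type, -0.19 and -0.13 in Shank3 vehicle, and 0.05 and 0.09 with GSK-LSD1.

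A small set of genes was higher in mutants given GSK-LSD1 than in those given vehicle. Hap1, a huntingtin-associated trafficking protein on chromosome 11 from 100347327 to 100356128 (minus strand), rose from 94.0 ± 6.93 to 225 ± 10.1 CPM (log2 fold change 1.26 ± 0.12, n = 2 libraries per group, edgeR adjusted p = 3.90e-05). Baiap3, which takes part in dense-core vesicle release and lies on chromosome 17 from 25242659 to 25256364 (minus strand), rose from 9.24 ± 3.32 to 47.0 ± 6.51 CPM (2.35 ± 0.21, adjusted p = 3.43e-04). Prph, the intermediate filament peripherin, rose from 1.05 ± 0.700 to 7.46 ± 0.534 CPM (2.82 ± 0.38, adjusted p = 0.00301), and Zcchc12 rose from 47.0 ± 6.42 to 84.8 ± 12.2 CPM (0.85 ± 0.12). In wild type the 4 genes lay at 112 ± 18.1, 8.07 ± 0.983, 0.666 ± 0.124 and 42.8 ± 1.76 CPM in that order, so the treated mutants were above both vehicle groups. In all, 20 genes passed, 19 higher and 1 lower.

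Other genes that rose with the inhibitor were the calcium sensor Doc2b (1.07 ± 0.17), the kinase Nek10 (1.5 ± 0.22), the Bardet-Biedl gene Bbs9 (0.62 ± 0.11) and Dpyd, the first enzyme of pyrimidine breakdown (1.01 ± 0.18). Wfs1, an endoplasmic reticulum protein, rose from 76.8 ± 0.948 to 115 ± 5.36 CPM (0.59 ± 0.10), against 125 ± 9.19 in wild type. Atp6v0c, a proton pump subunit, rose from 61.1 ± 0.484 to 105 ± 20.1 CPM (0.79 ± 0.12), against 113 ± 0.360 in wild type. The histone gene Hist1h4c belongs to a multicopy family whose reads can be split between copies, so its rise (0.70 ± 0.13) is uncertain. Markers of hypothalamus, septum and preoptic area, a list chosen after the data were seen, were positive for 15 of 15 measured members in this comparison. Their median was 0.71, with none passing edgeR's test over all genes (3 at an unadjusted p under 0.05, 0 by DESeq2 or limma-voom) and 2 higher adjusted over the list alone (camera adjusted p = 3.1e-08, and adjusted p = 0.28 with an estimated correlation). Between the libraries this list lay at 0.23 and 0.75 with GSK-LSD1, -0.18 and -0.07 in Shank3 vehicle, and -0.24 and -0.42 in wild type. Its median was 0.30 without GSK-LSD1 library 2, 1.17 without GSK-LSD1 library 1 and 0.35 without Shank3 vehicle library 1.

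Immediate early genes were the list with the smallest p. Egr2 rose from 2.99 ± 0.198 to 15.5 ± 4.18 CPM (2.36 ± 0.24, adjusted p = 1.07e-04) and Egr4 from 15.1 ± 0.986 to 28.2 ± 4.98 CPM (0.89 ± 0.15, adjusted p = 0.0238). Of the 25 members 23 did not pass over all genes, 23 were positive, and 8 rose adjusted over the list alone. Sik1 (0.76 ± 0.18) and Btg2 (1.36 ± 0.26) had the next smallest p and failed the adjustment over all genes. The list's median was 0.70 (camera adjusted p = 3.68e-25, and adjusted p = 0.256 with an estimated correlation). Levels of the list also differed within groups: the 2 GSK-LSD1 libraries lay at 0.18 and 0.48, the wild-type libraries at -0.20 and 0.23. Without GSK-LSD1 library 2 the list's median was 0.42. The 19 glucocorticoid-responsive genes were also called higher, with a median of 0.19 and 15 positive (adjusted p = 0.00110, and adjusted p = 0.405 with an estimated correlation). Of them 0 passed edgeR's test over all genes (4 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom) and 1 was higher adjusted over the list alone, with Per1 at 0.62 ± 0.13 (adjusted p = 0.0795 over all genes). Their median was 0.29 without Shank3 vehicle library 2 and 0.10 without GSK-LSD1 library 2.

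**Figure D2:**
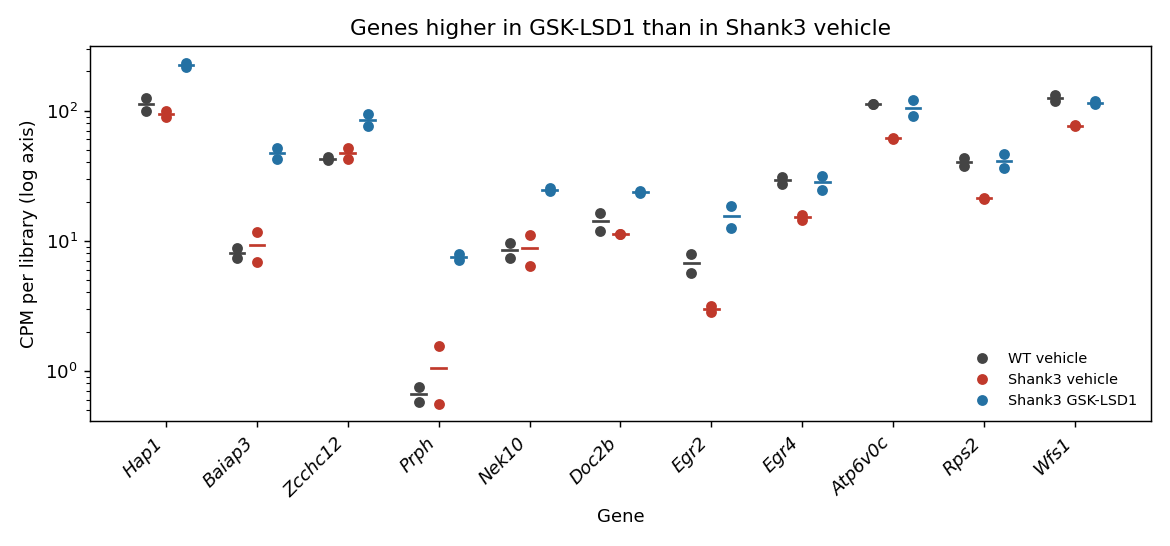
CPM on a log axis for 11 genes that rose with GSK-LSD1; points are single libraries and short bars group means of 2 libraries. Hap1, Baiap3, Zcchc12, Prph and Nek10 lie higher in both GSK-LSD1 libraries than in all 4 vehicle libraries, whereas Egr4, Atp6v0c, Rps2 and Wfs1 lie near the wild-type level after treatment. The sum of Rps2 and its processed copy was 41.3, 40.6 and 42.0 CPM in wild type, Shank3 vehicle and GSK-LSD1. The values of Rps2 alone are therefore uncertain and do not show a change in its expression.

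Of the 186 genes lower in Shank3 vehicle than in wild type, 6 rose with GSK-LSD1: Wfs1, Egr4, Egr2, Gaa, Atp6v0c and Rps2. Were the calls of both comparisons independent, 0.189 genes would be shared, but both use the Shank3 vehicle libraries. In 20 simulated runs of unchanged groups that share them up to 7 genes passed in both comparisons in opposite directions. Sharing alone can thus give an overlap of this size. The 7 is the largest of these runs, and their usual number is not given here. The gene Rps2, a ribosomal protein on chromosome 17 from 24718116 to 24721929, fell from 40.1 ± 3.83 CPM in wild type to 21.2 ± 0.283 in Shank3 vehicle (-0.92 ± 0.14) and stood at 41.3 ± 7.21 with GSK-LSD1 (0.96 ± 0.14). The single gene that fell with GSK-LSD1, Rps2-ps10, is its processed copy on chromosome 18 from 61259008 to 61259972, and was named after its values were seen. It lay at 1.13 ± 0.0432, 19.5 ± 3.8 and 0.706 ± 0.158 CPM in wild type, Shank3 vehicle and GSK-LSD1. The sum of Rps2 and the copy was 41.3 ± 3.79, 40.6 ± 3.52 and 42.0 ± 7.36 CPM. Both changes of Rps2 were thus matched by opposite changes of the copy. The values of Rps2 alone are uncertain and do not show a change in its expression. Reads of Atp6v0c, on chromosome 17 from 24163866 to 24169702 (minus strand), can also be shared with its copy Atp6v0c-ps2, and their sum was 312 ± 6.74, 242 ± 14.6 and 283 ± 51.0 CPM. That Atp6v0c, Rps2 and Baiap3 lie near each other was noticed after their values were seen. The wild type is described as a cross of C57BL/6 and C3H, and differences in sequence on that chromosome between animals were not tested from reads.

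**Figure D3:**
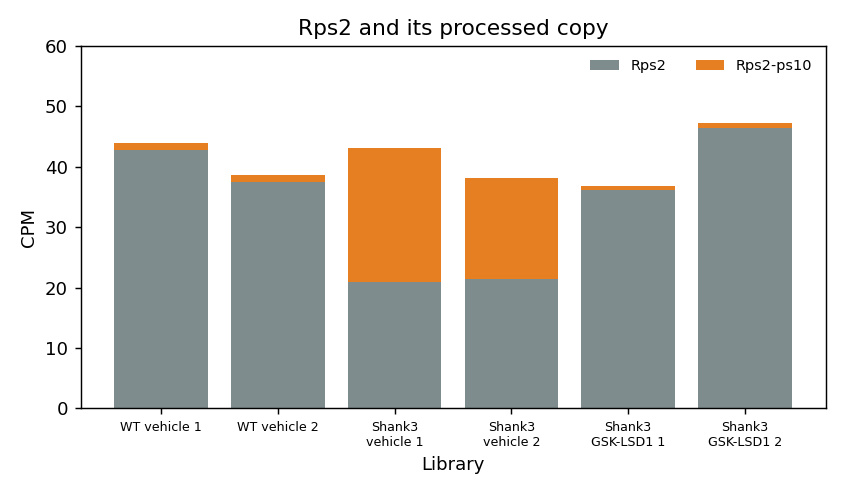
Stacked bars give the CPM of Rps2 (grey) and of its processed copy Rps2-ps10 (orange) in each of the 6 libraries. The copy takes 22.2 and 16.8 CPM in the Shank3 vehicle libraries and at most 1.16 CPM in the other 4.

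The channel, presynaptic and autism risk lists did not move toward wild type with the inhibitor. No member of the 3 lists passed edgeR's test over all genes or over the list alone (6, 3 and 4 at an unadjusted p under 0.05, 0 by DESeq2 or limma-voom), with medians of -0.10, -0.08 and -0.07. Camera called all 3 lower (adjusted p = 0.00167, 0.00993 and 0.0226; adjusted p = 0.431, 0.471 and 0.337 with an estimated correlation). Cytosolic ribosomal proteins (median 0.14, 41 of 48 positive, only Rps2 passing, 1 adjusted over the list alone) and the respiratory chain (0.11, 49 of 52 positive, 0 passing over all genes or over the list alone, 2 at an unadjusted p under 0.05, 0 by DESeq2 or limma-voom) were called higher. Their adjusted p-values were 2.35e-06 and 2.64e-05 (adjusted p = 0.577 and 0.658 with an estimated correlation). Oligodendrocyte markers had a median of -0.46 (adjusted p = 2.44e-04, and adjusted p = 0.601 with an estimated correlation), with 0 of 14 passing over all genes or over the list alone, 0 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom. Without GSK-LSD1 library 1 it was 0.06 and without library 2 -1.24. Erythrocyte markers had a median of -1.77, with Hba-a2 at 10.8 ± 5.26 and 2.04 ± 1.26 CPM and 0 of 5 passing over all genes or over the list alone, at an unadjusted p under 0.05, or by DESeq2 or limma-voom (adjusted p = 2.36e-06, and adjusted p = 0.359 with an estimated correlation). The LSD1-CoREST list had a median of 0.05 and was not called (adjusted p = 0.321). Ependymal markers, also not called, had a median of 0.15 with the test pointing lower, and were called without GSK-LSD1 library 1 (0.72) or 2 (-1.33). Several of these calls rested on single libraries: the presynaptic call was lost without Shank3 vehicle library 1 (median -0.04) or GSK-LSD1 library 2 (-0.01), and the autism risk call without either of them (-0.07 each). The ribosomal call was lost without Shank3 vehicle library 2 (0.08) or GSK-LSD1 library 2 (0.01), and that of the respiratory chain without Shank3 vehicle library 2 (0.01). Without Shank3 vehicle library 1 these medians were 0.21 and 0.21, without GSK-LSD1 library 1 the ribosomal median was 0.26 and the presynaptic median -0.12, and without Shank3 vehicle library 2 the erythrocyte median was -1.16.

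The other synaptic lists were not called between treated and untreated mutants. The medians were 0.02 for ionotropic glutamate receptors (9 of 17 positive, adjusted p = 0.773), 0.06 for monoamine, acetylcholine and peptide receptors (23 of 38 positive, adjusted p = 0.0567), -0.05 for postsynaptic scaffolds (6 of 30 positive, adjusted p = 0.0798) and -0.03 for GABA receptors (6 of 14 positive, adjusted p = 0.744). In each 0 members passed edgeR's test over all genes or over the list alone, with 0, 8, 0 and 1 at an unadjusted p under 0.05 in that order and 0 by DESeq2 or limma-voom. The monoamine, acetylcholine and peptide receptors were called higher without Shank3 vehicle library 1 (0.04) or GSK-LSD1 library 2 (0.10). Without GSK-LSD1 library 1 the postsynaptic scaffolds (-0.09) and GABA receptors (-0.14) were called lower, and the medians of the monoamine and ionotropic lists were -0.02 and -0.01. The GABA receptor median was also 0.01 without Shank3 vehicle library 1, -0.07 without library 2 and 0.08 without GSK-LSD1 library 2. That of ionotropic receptors was 0.02 and 0.04 without Shank3 vehicle library 1 and 2, and that of postsynaptic scaffolds -0.07 and -0.01 without Shank3 vehicle library 1 and GSK-LSD1 library 2.

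Further lists were called between treated and untreated mutants. Upper cortical layer markers had a median of 0.13 with 8 of 9 positive (adjusted p = 8.10e-04, and adjusted p = 0.471 with an estimated correlation), and striatal projection neuron markers 0.12 with 10 of 12 positive (adjusted p = 0.0146, and adjusted p = 0.337 with an estimated correlation). Choroid plexus markers had a median of 0.62 with 5 of 5 positive (adjusted p = 0.0146, and adjusted p = 0.530 with an estimated correlation), and endothelial markers -0.19 with 10 of 13 negative (adjusted p = 0.00328, and adjusted p = 0.50 with an estimated correlation). Interferon response genes had a median of 0.21 (adjusted p = 0.0146, and adjusted p = 0.337 with an estimated correlation) and extracellular matrix genes 0.12 (adjusted p = 0.0430, and adjusted p = 0.677 with an estimated correlation). In these 6 lists 0 genes passed edgeR's test over all genes (3, 2, 1, 4, 3 and 6 at an unadjusted p under 0.05, and 1 matrix gene by DESeq2 and 1 by limma-voom). Adjusted over the list alone 1 upper layer marker, 1 choroid plexus marker and 2 matrix genes were higher. The upper layer call was lost without Shank3 vehicle library 1 (0.01) or GSK-LSD1 library 1 (0.05), and its median was 0.28 and 0.21 without the other library of each group. The striatal call was lost without Shank3 vehicle library 2 (0.07) or GSK-LSD1 library 1 (0.08), and the interferon call without GSK-LSD1 library 1 (0.07). The choroid plexus call was lost without wild-type library 1 (0.44), Shank3 vehicle library 1 (0.06) or GSK-LSD1 library 2 (-0.67), with 1.08 and 1.24 without Shank3 vehicle library 2 and GSK-LSD1 library 1. The endothelial call was lost without Shank3 vehicle library 2 (0.03) or GSK-LSD1 library 2 (0.04), with -0.32 and -0.41 without library 1 of each group. The matrix call was lost without either wild-type library (0.12 each), Shank3 vehicle library 1 (0.03) or GSK-LSD1 library 1 (0.07), with 0.30 and 0.24 without Shank3 vehicle library 2 and GSK-LSD1 library 2.

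The remaining lists were not called between treated and untreated mutants. Medians were -0.05 for excitatory and 0.07 for inhibitory neuron, 0.01 for astrocyte, -0.00113 for oligodendrocyte precursor (0.01 with library size scaling), -0.02 for microglia, -0.04 for pericyte, 0.50 for meningeal and -0.14 for deep layer markers. They were -0.02 for actin regulators, 0.01 for heat shock genes and 0.02 for histone modifiers. No member passed edgeR's test over all genes (0 to 5 per list at an unadjusted p under 0.05, 0 by DESeq2, 1 meningeal marker by limma-voom), and 2 meningeal markers were higher and 1 microglia marker lower adjusted over the list alone. Single libraries decided several calls. Without GSK-LSD1 library 1 excitatory neuron (-0.14), astrocyte (0.09) and meningeal markers (-0.57) and actin regulators (-0.06) were called, and without its library 2 precursor (-0.09) and meningeal markers (0.95). Without Shank3 vehicle library 1 deep layer markers (0.30), microglia markers (-0.15) and heat shock genes (0.12) were called, and without its library 2 deep layer (-0.48) and meningeal markers (0.61).

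Left-out libraries moved the count to 11 without Shank3 vehicle library 1, 10 without library 2 and 83 (34 higher, 49 lower) without GSK-LSD1 library 2. Hap1, Baiap3, Prph, Nek10 and Egr2 passed in each of the fits made.

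Mutants given GSK-LSD1 still differed widely from wild type. Baiap3 (2.55 ± 0.22, n = 2 libraries per group, edgeR adjusted p = 5.38e-04), Hap1 (1.01 ± 0.12), Prph (3.51 ± 0.41) and Zcchc12 (0.98 ± 0.12) rose above wild type. Scube1 remained lower at 56.9 ± 2.28 CPM (-0.89 ± 0.11, adjusted p = 5.38e-04), as did Grin2b at 901 ± 3.56 CPM (-0.87 ± 0.13) and Pclo at 494 ± 40.7 CPM (-0.93 ± 0.13). The potassium channel Kcnq3 fell from 313 ± 8.64 to 188 ± 3.82 CPM (-0.73 ± 0.10). In all, 491 genes passed, 119 higher and 372 lower in treated mutants.

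Of 40 channels 16 fell (23 adjusted over the list alone; median -0.31), including Kcnq3, Cacna1d (-0.71 ± 0.12) and Cacna1g (-0.76 ± 0.12), with an adjusted p of 1.28e-22 (adjusted p = 0.256 with an estimated correlation). Of 49 autism risk genes 9 fell (25 adjusted over the list alone; median -0.27), including Setd5 (-0.50 ± 0.11), with an adjusted p of 8.70e-16 (adjusted p = 0.180 with an estimated correlation). Of 30 postsynaptic scaffolds 8 fell (12 adjusted over the list alone), including Dlgap2 (-0.53 ± 0.10) and Sorbs2 (-0.51 ± 0.10), and of 30 presynaptic proteins 7 (14 adjusted over the list alone), including Vamp2 (-0.69 ± 0.12). Their medians were -0.20 and -0.28 (adjusted p = 1.01e-10 and 5.65e-13, and adjusted p = 0.337 and 0.256 with an estimated correlation). Of 10 excitatory neuron markers 3 fell (5 adjusted over the list alone), among them Tbr1 (-0.54 ± 0.12) and Nrgn (-0.41 ± 0.11), with a median of -0.31 (adjusted p = 1.91e-06, and adjusted p = 0.315 with an estimated correlation). Of 12 astrocyte markers 4 rose (9 adjusted over the list alone), among them Aldoc (0.56 ± 0.13) and Aldh1l1 (0.47 ± 0.12), with a median of 0.48 (adjusted p = 1.61e-10, and adjusted p = 0.351 with an estimated correlation). Among histone modifiers Kmt2e (-0.52 ± 0.10), Setd5, Kmt2a (-0.74 ± 0.15) and Kmt5a (-0.63 ± 0.15) fell, 4 of 38 over all genes and over the list alone, with a median of -0.15 (adjusted p = 3.32e-05, and adjusted p = 0.351 with an estimated correlation). Hypothalamus, septum and preoptic area markers, chosen after the data were seen, had a median of 1.03 with Zic4 the 1 that rose over all genes and 9 adjusted over the list alone (adjusted p = 5.7e-06, and adjusted p = 0.23 with an estimated correlation), and a median of 0.53 without GSK-LSD1 library 2.

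The respiratory chain was higher in treated mutants than in wild type for 52 of 52 members, with a median of 0.24 (adjusted p = 2.48e-12, and adjusted p = 0.50 with an estimated correlation); Ndufa4 rose (0.43 ± 0.11), and 6 rose adjusted over the list alone. Erythrocyte markers had a median of -2.33 with 5 of 5 negative, 0 passing edgeR's test over all genes or over the list alone, 4 at an unadjusted p under 0.05, and 3 each by DESeq2 and limma-voom (adjusted p = 1.47e-05, and adjusted p = 0.405 with an estimated correlation). Oligodendrocyte precursor markers had a median of 0.36 with 10 of 10 positive, 0 passing edgeR's test, 5 at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma-voom and 3 higher adjusted over the list alone (adjusted p = 1.97e-04, and adjusted p = 0.351 with an estimated correlation). Microglia markers had a median of 0.23 with 13 of 14 positive, 0 passing edgeR's test, 4 at an unadjusted p under 0.05, 0 by DESeq2 or limma-voom and 1 higher adjusted over the list alone (adjusted p = 0.00312, and adjusted p = 0.530 with an estimated correlation). Oligodendrocyte markers had a median of 0.55 with 14 of 14 positive, and 0 passing edgeR's test over all genes or over the list alone, at an unadjusted p under 0.05, or by DESeq2 or limma-voom (adjusted p = 0.0427, and adjusted p = 0.778 with an estimated correlation). Ribosomal proteins had a median of 0.17 with 40 of 48 positive, 0 passing edgeR's test over all genes or over the list alone, 6 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom (adjusted p = 3.72e-04, and adjusted p = 0.658 with an estimated correlation). The precursor median was 0.55 without GSK-LSD1 library 1. The microglia call was lost without wild-type library 1 (0.06) or GSK-LSD1 library 1 (0.17), with 0.37 without wild-type library 2. The oligodendrocyte call was lost without wild-type library 2 (0.34) or either Shank3 vehicle library (0.55 each), with 1.04 and -0.19 without GSK-LSD1 library 1 and 2. The ribosomal call was lost without GSK-LSD1 library 2 (0.07), with 0.28 without library 1.

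Of 17 ionotropic glutamate receptors 5 fell against wild type (8 adjusted over the list alone), among them Grin2a (-0.54 ± 0.11) and Grin1 (-0.44 ± 0.11), with a median of -0.24 (adjusted p = 1.55e-08, and adjusted p = 0.256 with an estimated correlation). Of 14 GABA receptors 3 fell over all genes and over the list alone, among them Gabbr2 (-0.59 ± 0.12), with a median of -0.17 (adjusted p = 2.87e-04, and adjusted p = 0.471 with an estimated correlation). Of 38 monoamine, acetylcholine and peptide receptors Adra1b (-0.71 ± 0.14) and Chrm1 (-0.51 ± 0.11) fell and Oxtr rose (0.80 ± 0.21), with 7 lower and 2 higher adjusted over the list alone and a median of -0.12 (adjusted p = 0.00431, and adjusted p = 0.50 with an estimated correlation). Of 32 actin regulators 4 fell (7 adjusted over the list alone), among them Wasl (-0.41 ± 0.10), with a median of -0.08, or 0.00121 with library size scaling (adjusted p = 0.00193, and adjusted p = 0.471 with an estimated correlation). Without wild-type library 1 the ionotropic median was -0.15 and the GABA median -0.29, and the monoamine call was lost (-0.08). Without wild-type library 2 the GABA call was lost (-0.09) and the monoamine median was -0.20. Without GSK-LSD1 library 1 the GABA, monoamine and actin medians were -0.36, -0.22 and -0.17, and without library 2 all 3 calls were lost (-0.08, -0.08 and 0.00385).

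Not called against wild type were markers of upper layers (0.09), deep layers (-0.21), inhibitory neurons (0.09), striatal neurons (0.15), pericytes (0.11), endothelium (0.09), meningeal fibroblasts (0.35) and ependymal cells (0.39). Nor were matrix genes (0.13), heat shock genes (0.06) or the LSD1-CoREST list (-0.04, or 0.04 with library size scaling). Of these lists' genes Rspo1 (1.78 ± 0.38) and Sparc (0.45 ± 0.12) rose and Tnr fell (-0.55 ± 0.11). Without GSK-LSD1 library 1 ependymal (1.33) and meningeal markers (-0.53) were called, and without library 2 meningeal (0.69) and upper layer markers (0.19) and matrix genes (0.24).

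Immediate early genes in treated mutants had a median of 0.26 against wild type, with Egr2 (1.17 ± 0.23) and Sik1 (0.74 ± 0.18) higher and Nptx2 lower (-0.47 ± 0.12), and 4 higher and 2 lower adjusted over the list alone (adjusted p = 0.00406, and adjusted p = 0.580 with an estimated correlation). That call was lost without GSK-LSD1 library 2 (median 0.23), and the median was 0.15 without wild-type library 1, 0.63 without wild-type library 2 and 0.51 without GSK-LSD1 library 1. The count of genes was 6 without wild-type library 1 and 197 without GSK-LSD1 library 2, and scaling by library size alone gave 111 higher and 142 lower genes. The correction for length and GC content left 113 higher and 216 lower genes, and the lower genes had a median exonic length of 8.12 kb.

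Both comparisons with wild type shared 143 lower genes and 19 higher genes. The comparisons share the wild-type libraries, so part of this overlap comes from them, and how large that part is was not tested. The 186 genes lower in Shank3 vehicle had a median log2 fold change of -0.01 between treated and untreated mutants, and 48.4% moved toward wild type. Against wild type their median was -0.56 in each GSK-LSD1 library. The 52 genes higher in Shank3 vehicle had a median of -0.22 with treatment, with 84.6% moving toward wild type, and 0.50 against wild type. Genes were chosen on the Shank3 vehicle libraries, so a return toward wild type arises in part by chance.

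Across all 18705 genes, which are not independent replicates, the log2 fold changes of treatment and genotype had a correlation of r = -0.40. It was -0.65 and -0.64 without Shank3 vehicle library 1 and 2, -0.26 without wild-type library 2 and -0.24 without GSK-LSD1 library 1. Simulated unchanged groups that share the Shank3 vehicle libraries gave r = -0.49 (SD 0.00841, 20 runs). The observed covariance was -0.0765 against a simulated -0.0667. With the Shank3 vehicle libraries split so that each comparison used another one, the mean covariance was -0.00598, against -0.0626 on the same log-CPM scale without the split. The observed r was no stronger than the simulated one and the covariance fell close to 0 with the split, so most of the relation goes with the shared libraries.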

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

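The length and GC correction and the oligodendrocyte covariate were chosen after the data were seen; the other settings were planned. The cause of a change was not tested except where fewer libraries, genes tested or a looser threshold are the setting itself. The 238 calls of Shank3 vehicle against wild type became 35 with library size scaling, 141 with upper quartile scaling, 807 without a filter, 602 with DESeq2, 137 with limma-voom, 11 without the robust option, 524 from only the 4 libraries, 61 with the length and GC correction, 100 (6 higher, 94 lower) with the oligodendrocyte covariate, 552 at an adjusted p under 0.10 and 2363 at an unadjusted p under 0.05 with a fold of at least 1.2. The 20 calls of GSK-LSD1 against Shank3 vehicle became 106 without a filter, 35 with DESeq2 and 956 at the unadjusted threshold. The 491 calls of GSK-LSD1 against wild type became 253 with library size scaling, 962 without a filter, 782 with DESeq2, 871 at an adjusted p under 0.10 and 2668 at the unadjusted threshold. Leaving out 1 library gave 6 to 656, 10 to 83 and 6 to 631 calls in the 3 comparisons, with the lone library of a group assumed to vary like the others; the lowest values of the first and last came without wild-type library 1. The correlation of treatment and genotype effects, -0.40, was -0.59 with the oligodendrocyte covariate and ran from -0.65 to -0.24 with 1 library left out. The 55 called list tests became 0 with an estimated correlation and 0 with fry, and ran from 48 to 56 with 1 library left out.

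Medians of lists called with or without the change turned sign as follows. With library size scaling, actin regulators went to 0.0289 in Shank3 vehicle against wild type and to 0.00121 in GSK-LSD1 against wild type. With the oligodendrocyte covariate, in Shank3 vehicle against wild type, actin regulators went to 0.0828, ribosomal proteins to -0.15, ependymal markers to -0.99, GABA receptors to 0.0264 and meningeal markers to 0.97. With 1 library left out, deep layer markers ran from -0.44 to 0.25 in Shank3 vehicle against wild type. In GSK-LSD1 against Shank3 vehicle the ranges were -0.67 to 1.24 for choroid plexus, -0.48 to 0.30 for deep layers, -0.41 to 0.0378 for endothelial, -1.33 to 0.72 for ependymal, -0.57 to 0.95 for meningeal and -1.24 to 0.0575 for oligodendrocyte markers. In GSK-LSD1 against wild type they were -0.17 to 0.00385 for actin regulators, -0.24 to 1.59 for choroid plexus, -0.53 to 0.69 for meningeal and -0.19 to 1.04 for oligodendrocyte markers. Among lists called in neither case, library size scaling turned deep layer markers (0.04) and matrix genes (0.04) in Shank3 vehicle against wild type, oligodendrocyte precursor markers (0.01) in GSK-LSD1 against Shank3 vehicle and the LSD1-CoREST list (0.04) in GSK-LSD1 against wild type; other such lists turned with single libraries left out or other settings, and are not listed.

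No named gene changed sign where either fit called it. Over all settings 7653 gene values stayed on the same side of the threshold, 597 lost the call and 205 gained one. Changes of sign among values called in neither fit were not counted. The replicate numbers were not shown to pair the samples (deviation correlations -0.0797, -0.0699 and 0.157), and with the replicate block 233, 18 and 505 genes passed. Low counts limit genes under about 1 CPM, and 2 libraries per group limit every test.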

Other observations

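The correction for length and GC content and the model with the oligodendrocyte level were chosen after the data were seen, though the bounds for reading them in the 186 lower genes and the immediate early genes were set before their results. The tests of neuron markers, of the state of the animals, of region markers, of length and GC content in the other treatment genes, of Rps2 and of name-prefix families were chosen after the result was seen.

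Of 66 measured protocadherins, adhesion proteins of neurons and a family chosen after the data were seen, 3 fell in Shank3 vehicle (Pcdh19, Pcdhgc5 and Pcdh1; median -0.29, camera adjusted p = 2.4e-09, and adjusted p = 0.39 with an estimated correlation). With GSK-LSD1 8 fell against wild type (median -0.42, adjusted p = 6.0e-15, and adjusted p = 0.23 with an estimated correlation), and the direction was the same under each scaling and with each library left out. Histone genes had a median of 0.38 with GSK-LSD1 against Shank3 vehicle, with 47 of 53 positive and only Hist1h4c passing (adjusted p = 1.5e-12, and adjusted p = 0.44 with an estimated correlation); without GSK-LSD1 library 2 the median was 0.10 and without library 1 0.57. Between Shank3 vehicle and wild type the medians of other families were 0.04 for 366 zinc finger genes, 0.07 for 39 proteasome subunits, 0.30 for 41 collagens, -0.14 for 31 semaphorins and plexins, 0.10 for 44 ankyrins, spectrins and kinesins and -0.02 for 19 vacuolar ATPase subunits (0.05 with library size and 0.00104 with upper quartile scaling). They were 0.14 for 11 complement and Fc receptor genes, 0.07 for 14 MHC genes, 0.07 for 25 small nuclear and nucleolar RNAs, -0.51 for 4 haemoglobins, 0.37 for 10 thalamus markers and -0.13 for 53 histone genes. Camera called only the collagens (adjusted p = 0.022, and adjusted p = 0.69 with an estimated correlation) and the semaphorins and plexins (adjusted p = 0.0071, and adjusted p = 0.69 with an estimated correlation) among these. The collagen call was lost without wild-type library 2 (0.26) or Shank3 vehicle library 2 (0.09), with 0.49 without Shank3 vehicle library 1. That of semaphorins and plexins was lost without wild-type library 1 (-0.05), with -0.23 without wild-type library 2, -0.08 without Shank3 vehicle library 1 and -0.06 with library size scaling. Without Shank3 vehicle library 1 histone genes (-0.27), vacuolar ATPase subunits (-0.09) and thalamus markers (0.38) were called, and without library 2 proteasome subunits (0.15).

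Other families were also called between treated and untreated mutants. Protocadherins were called lower (median -0.12, adjusted p = 0.0098, and adjusted p = 0.45 with an estimated correlation), as were ankyrins, spectrins and kinesins (-0.08, adjusted p = 0.0099, and adjusted p = 0.28 with an estimated correlation) and haemoglobins (-1.95, adjusted p = 7.7e-06, and adjusted p = 0.42 with an estimated correlation). Proteasome subunits (0.08, adjusted p = 0.025, and adjusted p = 0.79 with an estimated correlation) and complement and Fc receptor genes (0.24, 11 of 11 positive, adjusted p = 0.022, and adjusted p = 0.45 with an estimated correlation) were called higher. In these 5 families 0 genes passed edgeR's test (6, 3, 0, 1 and 2 at an unadjusted p under 0.05, 0 by DESeq2 or limma-voom). The protocadherin call was lost without Shank3 vehicle library 1 (-0.14) or GSK-LSD1 library 1 (-0.09), with -0.21 without GSK-LSD1 library 2, and the kinesin group's without Shank3 vehicle library 2 (-0.08) or GSK-LSD1 library 1 (-0.07). The proteasome call was lost without Shank3 vehicle library 2 (-0.03) or GSK-LSD1 library 1 (0.03), with 0.18 without Shank3 vehicle library 1. The complement call was lost without Shank3 vehicle library 1 (0.13) or GSK-LSD1 library 2 (0.20), with 0.44 without Shank3 vehicle library 2. Zinc finger genes (-0.04), small nuclear and nucleolar RNAs (-0.02), vacuolar ATPase subunits (0.02), collagens (-0.04), MHC genes (-0.10), semaphorins and plexins (-0.00214, or 0.01 with library size scaling) and thalamus markers (0.22) were not called. Vacuolar ATPase subunits were called without Shank3 vehicle library 1 (0.15) or GSK-LSD1 library 2 (0.14), MHC genes without GSK-LSD1 library 1 (-0.65) and thalamus markers without Shank3 vehicle library 2 (0.34).

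Between treated mutants and wild type, camera called higher the histone genes (0.34, with Hist1h4i rising, adjusted p = 5.9e-05, and adjusted p = 0.48 with an estimated correlation), proteasome subunits (0.15, adjusted p = 0.0027, and adjusted p = 0.65 with an estimated correlation), collagens (0.28, adjusted p = 0.010, and adjusted p = 0.33 with an estimated correlation), complement and Fc receptor genes (0.32, adjusted p = 0.0049, and adjusted p = 0.33 with an estimated correlation) and thalamus markers (0.50, adjusted p = 0.0045, and adjusted p = 0.33 with an estimated correlation). It called lower the semaphorins and plexins (-0.14, with Plxna4 and Plxna1 falling, adjusted p = 0.0017, and adjusted p = 0.33 with an estimated correlation) and haemoglobins (-2.41, adjusted p = 8.7e-05, and adjusted p = 0.33 with an estimated correlation). Among proteasome, collagen, complement, thalamus and haemoglobin genes 0 passed edgeR's test, with 5, 9, 3, 4 and 3 at an unadjusted p under 0.05, 0, 1, 1, 1 and 3 by DESeq2, and 3 haemoglobins by limma-voom. The histone call was lost without GSK-LSD1 library 2 (-0.02), with 0.55 without library 1. The proteasome call was lost without wild-type library 1 (0.10) or GSK-LSD1 library 1 (0.09), the collagen call without wild-type library 2 (0.27) or GSK-LSD1 library 1 (0.12), and that of semaphorins and plexins without wild-type library 1 (-0.06), with -0.23 without wild-type library 2. The thalamus median was 0.29 without GSK-LSD1 library 2. Not called were small nuclear and nucleolar RNAs (0.18) and 4 families that library size scaling turned positive: zinc finger genes (-0.01 to 0.07), vacuolar ATPase subunits (-0.01 to 0.07), MHC genes (-0.03 to 0.04) and ankyrins, spectrins and kinesins (-0.07 to 0.01). With upper quartile scaling the zinc finger and vacuolar ATPase medians were also positive, at 0.01 each. Vacuolar ATPase subunits were called without GSK-LSD1 library 2 (0.13) and MHC genes without GSK-LSD1 library 1 (-0.69).

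In treated mutants against wild type, interferon response genes had a median of 0.40 with Ifit1 rising (1.95 ± 0.47) and 5 higher adjusted over the list alone (adjusted p = 2.42e-04, and adjusted p = 0.256 with an estimated correlation). Glucocorticoid-responsive genes had a median of 0.35, with Mt1 (0.63 ± 0.12) and Tsc22d3 (0.61 ± 0.11) higher, Zbtb16 lower (-0.45 ± 0.11), and 8 higher and 1 lower adjusted over the list alone (adjusted p = 1.50e-05, and adjusted p = 0.337 with an estimated correlation). Choroid plexus markers had a median of 1.32 with Kl (1.32 ± 0.26) and Clic6 higher, 2 of 5 over all genes and over the list alone (adjusted p = 0.00406, and adjusted p = 0.50 with an estimated correlation), and -0.24 without GSK-LSD1 library 2. The call was also lost without wild-type library 1 (0.77) or 2 (1.59), and the median was 0.60 without Shank3 vehicle library 1. Clic6 lay below the counting floor in both wild-type libraries, so no fold change is given for it.

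The 186 genes lower in Shank3 vehicle than in wild type, longer than others (median exonic length 7.79 kb against 3.79 kb), had a median of -0.55 (quartiles -0.64 to -0.51). After correction for length and GC content the median was -0.46 (-0.53 to -0.39) with 35 still called (median SE 0.12 before and 0.10 after). With the oligodendrocyte level in the model it was -0.63 (-0.75 to -0.49) with 50 called and a median SE of 0.16. Why calls were lost was not tested. The genes were chosen for their fall in these same libraries, so a chance part survives the correction. The corrected median therefore cannot exclude length and GC content as the cause. The model's slope on the oligodendrocyte level came from differences within groups, mainly between the 2 GSK-LSD1 libraries (-0.67 and 0.59). It cannot separate the oligodendrocyte share from other differences between those libraries, so both explanations stay open. A smaller share of all neurons cannot be told apart, since inhibitory markers, 0.40 above excitatory ones (95% bootstrap interval 0.05 to 0.58 over marker genes, not libraries), went both ways (9 positive, 5 negative), and the interval held 0 without wild-type library 1 (-0.01 to 0.48), without Shank3 vehicle library 2 (-0.00446 to 0.55) and with the oligodendrocyte level in the model (-0.20 to 0.55). That, a loss of excitatory neurons or their RNA alone, a difference in dissection, and the genotype itself stay open, and each may hold for part of the genes.

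The immediate early genes had a median of 0.70 between treated and untreated mutants (quartiles 0.21 to 1.26). It was 0.61 after correction for length and GC content, which argues against that bias as the whole cause. With the oligodendrocyte level in the model the median was 0.78. The slope of that model came mainly from the 2 GSK-LSD1 libraries (oligodendrocyte levels -0.67 and 0.59), which also differed in the immediate early genes. That fit therefore cannot decide on the oligodendrocyte share. The state of the animals at collection (arousal, handling, time of day) cannot be told apart from the inhibitor, since it could follow the group, and the median difference over the list's genes between the 2 GSK-LSD1 libraries was 0.45. Glucocorticoid-responsive genes, with a median of 0.19 in the same comparison (adjusted p = 0.00110, and adjusted p = 0.405 with an estimated correlation), leave both open.

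The 17 other genes higher with GSK-LSD1 had a median of 1.01 (quartiles 0.79 to 1.21). After correction for length and GC content it was 1.04 (0.76 to 1.17) with 12 still called. The correction did not lower the median, but the genes were chosen for their rise in these same libraries. The value therefore cannot exclude that bias. Tissue from hypothalamus, septum or preoptic area in the treated samples is a candidate explanation, from the region's median of 0.71 over 15 of 29 listed markers. Of these, 13 had a mean of at least 1 CPM in wild type. None of the 17 genes is on that list, which carries no weight because the list was chosen after the data were seen. Between the GSK-LSD1 libraries (2 minus 1) the median log2 difference was 0.66 for the markers and 0.08 for the 17 genes. The genes thus did not follow the median of the markers within that group. The explanation need not require this, since the markers themselves went apart there: Zic1 differed widely between the 2 libraries, but Ngb, Cartpt and Irs4 little. The comparison also rests on a single pair of libraries and leaves the explanation open. Of the markers, the most abundant differed little or within the group: Resp18 lay at 42.5 and 37.3 CPM with GSK-LSD1 against 36.6 and 32.5 in Shank3 vehicle, and Zic1 at 15 and 49.3 against 12.1 and 24.8, while both treated libraries lay higher for Ngb (10.3 and 10.6 against 2.94 and 6.39), Cartpt (4.41 and 3.95 against 2.71 and 2.95) and Irs4 (1.82 and 1.5 against 0.735 and 0.499). Markers of upper layers (0.13), striatal neurons (0.12), choroid plexus (0.62) and endothelium (-0.19) were also called in this comparison, though each lost its call without at least 1 library and with an estimated correlation (adjusted p = 0.471, 0.337, 0.530 and 0.50), so a difference in dissection and an effect of the inhibitor stay open.

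For Rps2 and its processed copy, the log2 ratio of their summed CPM in Shank3 vehicle over wild type was -0.0226. Of 233 other copies named as processed 0 passed edgeR's test in that comparison, with 10 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom. The 6 genes lower in Shank3 vehicle and higher with GSK-LSD1 include Rps2 and Atp6v0c, 554250 bp apart on chromosome 17. Their nearness was seen first and prompted the test, so its permutation p of 0.0147 against random tested genes only restates it and counts for no explanation. Baiap3, which rose with GSK-LSD1, lies on the same chromosome from 25242659 to 25256364. Differences in sequence there between animals were not tested from reads.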
